A study of soil metagenome with 10 samples.

How the data were processed

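Soil was collected at Whapmagoostui-Kuujjuarapik in the sub-Arctic and stored in a stabilising solution, per the labels' protocols. DNA and RNA came from each of 5 soil samples, and the RNA was treated with DNase I and copied into first-strand cDNA, per the labels. The 5 DNA arrays and 5 cDNA arrays form the 2 groups, and the soil sample numbers 4, 6, 7, 13 and 14 are those of the labels. Per the labels' protocols, 500 ng of each sample was labelled with Cy3 by random priming and hybridised to GeoChip, a microarray of probes for microbial functional genes. The labels describe the 5 soil samples as biological replicates of a sampling site, so p-values measure the spread between these soil samples.

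The deposited scanner tables hold 1 spot per line with green and red intensity, local background and quality flags, made with Agilent Feature Extraction 12.0.3.2 and protocol GE2_1200_Jun14, per the file headers. The green channel holds the Cy3-labelled sample and the red channel gave signal for a universal standard on 1280 spots. Intensities were background-subtracted within each array by that software and not normalized between arrays, per the file headers. The deposited flags mark spots well above background, saturated spots and outliers, and these other columns hold 0 or 1. The authors' processed table holds a linear signal per probe and array, with the gene family, category and lineage of each probe. It has 100175 entries and 1253 gene families, and 38365 entries have a value on all 10 arrays. The authors' scaling method is not given in the sources used here. Its column totals, in units of 1e8, lay between 5.28 and 5.71 on scan date 1 and between 9.37 and 10.1 on scan date 2. Its column medians were 1242, 3079, 1197, 2941 and 1144 for DNA of soil samples 4, 6, 7, 13 and 14, and 1941, 5648, 1555, 5450 and 2093 for cDNA. Set against the scanner values of the same spots, the table is on a linear scale and runs in the same direction, while its centring between arrays stays unknown. Among proteins with 1 target probe, where this was checked, every value kept by the authors came from a spot with a mean intensity of at least 200.

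Each array has 180880 spots, of which 161963 are target probes. Probe names were matched to the processed table through the protein number in both. This gave 99309 target probes with 1 gene family, 2685 with several, which were left unnamed, and 59969 that the table does not list, which were also left unnamed. Gene families are printed in conventional letter case. Percentages per gene category are over the probes of that category in the processed table, which lists probes the authors kept on at least 1 array, and so run higher than percentages over all target probes.

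The software's processed green signal could not be used, because its multiplicative detrending step gave values without any physical range on these arrays. The background-subtracted green intensity took its place, a departure from the planned input. Each array was divided by its 75th percentile over all target probes, since a mean of 56.9% of them were well above background. Values were then raised to a common floor and put on the log2 scale. The floor was the highest, over the arrays, of the lowest scaled intensity among probes well above background, 0.300 of the 75th percentile or -1.74 on the log2 scale. This floor was chosen after the values had been looked at. Of the probes well above background on at least 4 of the 5 arrays of a group, 96737 in number, 2939 with an outlier spot on any array were left out, as were 3968 at the floor on every array. The remaining 89830 probes were tested, and 77571 of them have a gene family. Control spots were left out and saturated spots were kept. Depth here means signal over background, and the number of arrays limits the precision.

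The difference is cDNA minus DNA on the log2 scale throughout. Probes, gene families and lineages were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg adjusted p, threshold 0.05). A family or lineage value is the mean over its tested probes, with at least 3 probes for a family and 10 for a lineage. Gene lists fixed in advance, with at least 2 tested families, were tested on family values with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, and annotated subcategories with at least 10 probes were tested on probe values in the same way. The family annotated as mer was kept out of the methanogenesis list, because the table places it under mercury. Single values per array were compared with exact permutation tests over all 252 assignments of 5 against 5 arrays, two-sided, in Python 3.11.15 with SciPy 1.17.1, numpy 2.4.6 and pandas 2.3.3. Plots were drawn with matplotlib 3.10.9.

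The families named were, per direction, those with at least 5 tested probes that passed the threshold with the same sign in all 5 soil samples, up to 12 by size. With fewer than 3 passing in a direction, the 3 of smallest p were named. Up to 4 members of each list and 11 families chosen by name were reported whatever their value. Single probes named were the 5 of largest difference in each direction, past the threshold, with the same sign in all 5 soil samples. This last rule was narrowed, after the values had been looked at, to probes above background and above the floor on all 10 arrays, of which 2478 passed the threshold. The groups, tests, lists, naming rules and most other settings to be tried were fixed before the data were examined.

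DNA and RNA were extracted from the same soil sample, so the numbers pair the arrays, and a fit with the soil sample as a block was set beside the unpaired test. Probe deviations of DNA and cDNA of one soil sample correlated at 0.0430 to 0.109 (across probes), above 0.1 in 2 of 5 pairs. The arrays lay on 4 slides, which were taken from the scan times and matched the slide identifiers in the file headers for 9 arrays, the slide of 1 array (DNA of soil sample 14) resting on its scan time alone. They were scanned on 2 dates, 6 arrays (soil samples 4, 7 and 14) on scan date 1 and 4 (soil samples 6 and 13) on scan date 2, and both dates hold both groups. Slide 1 held DNA of soil samples 4, 7 and 14 and cDNA of 4. Slide 2 held cDNA of 7 and 14, slide 3 DNA of 6 and 13, and slide 4 cDNA of 6 and 13. Only slide 1 thus held both groups, and most comparisons of cDNA with DNA, all on scan date 2 included, were between slides. There a slide effect cannot be told apart from the difference of the groups. Settings chosen in advance were the soil sample as a block, normexp background correction with an offset of 50, quantile normalization, median scaling, the percentile over probes above background on all arrays, scaling by the red-channel standard, the authors' table, 2 other filters on dim probes, the slide as a random block, other limma settings, other family rules and leaving out each array in turn. Scan date as a block, each scan date alone, the data without soil sample 14, a floor per array and removal of a brightness trend (lowess span 0.3) were added after seeing the data. Values of single probes, families and lineages under another scaling, with a floor per array or over probes above background on all 10 arrays are given relative to the median shift of all probes, a choice made after seeing the data for the floor per array and the probes above background on all 10 arrays. A planned check of GC content was not run, because no spot carries a probe sequence.

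The limma and camera tests were checked on simulated data built from these arrays, and the exact permutation test on random normal values. Of 100 changed families, 34% were recovered at a log2 change of 0.5 and 89% at 1, with 6 of 3690 unchanged families called. All 10 shifted lists were recovered at 0.5. Of single probes, 0% were recovered at a change of 1 and 5.25% at 2. These shares hold for the changes set in the simulation and are not the recovery in the real data, where 4669 of 89830 probes passed. The exact permutation test passed 7% of 200 runs without a difference and 98% with a difference of 3 SD.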

Results

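Soil from a sub-Arctic site at Whapmagoostui-Kuujjuarapik was surveyed with GeoChip, a microarray that carries probes for functional genes of bacteria, archaea, fungi, protists and viruses. Genomic DNA, which records the genes a community carries, and cDNA made from its RNA, which records transcripts, were hybridised for each of 5 soil samples, numbered 4, 6, 7, 13 and 14. This gave 10 arrays, 5 of DNA and 5 of cDNA. The 75th percentile of background-subtracted intensity ranged from 966 to 4016 on DNA arrays (mean 2208) and from 239 to 477 on cDNA arrays (mean 319). Saturated spots numbered 685 to 1628 per DNA array and 45 to 704 per cDNA array. Values of cDNA therefore lay closer to background than those of DNA.

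The first comparison asked whether cDNA lit up fewer genes than DNA. Of 161963 target probes, 105225 ± 8167 were well above background in DNA and 79028 ± 7476 in cDNA (SD, n = 5 each), or 65.0% and 48.8%. Virus genes went from 77.5% ± 6.87 in DNA to 50.8% ± 8.98 in cDNA, and gyrB, the DNA gyrase gene used as a phylogenetic marker, from 84.3% ± 4.95 to 58.3% ± 7.73. Nitrogen cycling genes went from 87.4% ± 4.34 to 65.1% ± 6.89, carbon cycling genes from 85.9% ± 4.47 to 63.8% ± 7.25, and antibiotic resistance genes from 89.3% ± 3.95 to 70.98% ± 5.90. Pigment genes had the smallest gap of the 17 gene categories, from 90.1% ± 3.72 to 73.2% ± 5.88. All 17 categories were lower in cDNA in 5 of 5 soil samples and within both scan dates, each with an adjusted p of 0.00794 by the exact permutation test. In the test with the soil sample as the block 0 of 17 passed, each with an exact sign-flip p of 0.0625, the smallest that 5 pairs allow.

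The count over all probes fell by 26197 (exact permutation test, p = 0.00794, the smallest that 5 against 5 arrays allow), and the lowest DNA array, at 98285, lay above the highest cDNA array, at 89913. With the soil sample as the block, the sign-flip test of this count also gave an exact p of 0.0625. Within scan date 1 the means were 99557 in DNA and 83456 in cDNA (difference -16101), and within scan date 2 they were 113726 and 72385 (difference -41342). The cDNA arrays were also the dimmer ones, with a mean 75th percentile of 319 against 2208.

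**Figure D1:**
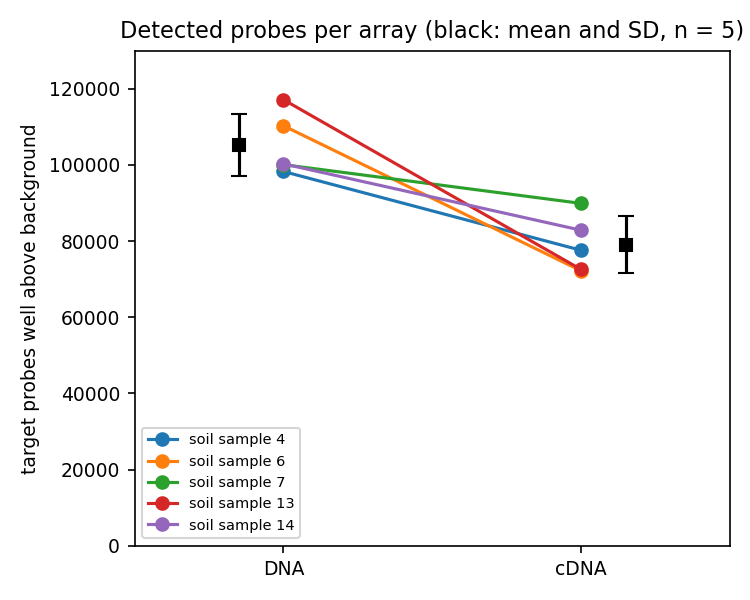
Target probes well above background on each array (vertical axis, count of probes), with 1 point per array, lines joining DNA and cDNA of a soil sample, and group means with SD. The 5 DNA arrays lie at or above 98285 and the 5 cDNA arrays at or below 89913.

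The share of total signal that each gene category took was compared next. Nitrogen cycling genes held 4.002% ± 0.0671 of the signal in DNA and 3.53% ± 0.261 in cDNA (SD, n = 5). Genes for degradation of organic contaminants held 9.20% ± 0.184 and 8.34% ± 0.281. Both were lower in 5 of 5 soil samples (exact permutation test, p = 0.00794, adjusted p = 0.0675 for each), within scan date 1 by -0.502 and -0.867 percentage points and within scan date 2 by -0.432 and -0.860. Pigment genes held 1.48% ± 0.0788 in DNA and 1.68% ± 0.172 in cDNA, higher in 5 of 5 soil samples (exact permutation p = 0.0238, adjusted p = 0.135). Central metabolic pathway genes held 0.840% ± 0.0366 and 0.741% ± 0.0697, lower in 5 of 5 (exact permutation p = 0.0317, adjusted p = 0.135). By the exact permutation test 0 of 17 categories passed after adjustment and 4 had an unadjusted p under 0.05. The count was 3 without the cDNA array of soil sample 7 and 3 without that of soil sample 13.

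The next comparison asked which gene families took a higher or lower place in cDNA than in DNA. The gene ccmM, which encodes a protein of the carboxysome, the compartment in which cyanobacteria and some other bacteria fix carbon dioxide, rose by 0.79 on the log2 scale (1.73-fold, SE 0.11, 6 probes), from -0.31 ± 0.13 in DNA to 0.48 ± 0.22 in cDNA (SD, n = 5). The family Ni_Fe_hydrogenase, enzymes that take up or release hydrogen, rose by 0.66 (1.58-fold, SE 0.12, 8 probes), from -0.90 ± 0.20 to -0.24 ± 0.19. The CRISPR-associated family csx14 rose by 0.56 (1.47-fold, SE 0.10, 5 probes), from -1.06 ± 0.17 to -0.49 ± 0.13. The family pbrA, which exports lead from the cell, fell by 1.06 (SE 0.20, 16 probes), from 1.04 ± 0.43 to -0.01 ± 0.26. The arsenite methyltransferase arsM fell by 0.37 (SE 0.07, 40 probes), from 0.04 ± 0.10 to -0.33 ± 0.05. It lay at 0.052 with the median over its probes in place of the mean.

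Each of these 5 families moved the same way in 5 of 5 soil samples, which the naming rule required of ccmM, Ni_Fe_hydrogenase and csx14. Limma adjusted p was 0.0144 for ccmM, 0.0283 for Ni_Fe_hydrogenase, csx14 and arsM, and 0.0306 for pbrA. Within scan dates 1 and 2 the differences were 0.66 and 0.99 for ccmM, 0.75 and 0.51 for Ni_Fe_hydrogenase, 0.59 and 0.52 for csx14, -1.092 and -1.004 for pbrA, and -0.43 and -0.28 for arsM. The third smallest p in the lower direction among families with at least 5 probes belonged to csb1, a CRISPR-associated family, which did not pass (-0.31, SE 0.07, adjusted p = 0.0531). Families with 3 or 4 probes made up the rest of the calls and were named after their values were seen. They were hxuB, part of a heme-hemopexin uptake system (1.31, SE 0.19), coat protein genes of pomoviruses (0.76, SE 0.12) and bymoviruses (0.86, SE 0.16), both of plant viruses, and primase (-1.27, SE 0.24). Within scan dates 1 and 2 these lay at 1.48 and 1.05, 0.96 and 0.46, 0.80 and 0.93, and -1.38 and -1.10.

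Of 778 families tested with limma, 9 passed, 6 higher and 3 lower, and 167 had an unadjusted p under 0.05, 63 higher and 104 lower. With the soil sample as a block 20 passed, 8 higher and 12 lower, 7 of them among the 9. The block ended the calls of the pomovirus coat protein (adjusted p = 0.0547) and primase (adjusted p = 0.0594). With scan date as a block 61 passed, 20 higher and 41 lower, and within scan date 1 or scan date 2 alone 0 passed.

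Alternative scalings moved the median of all probes, by -0.15 for median scaling, 0.15 for the percentile over probes above background on all arrays (common-probe scaling), 0.35 for normexp, -1.15 for the red-channel standard and 0.54 for the authors' table, and so did a floor per array (0.36) and the restriction to probes above background on all 10 arrays (0.17). The split of calls moved with them, from 6 higher and 3 lower to 1 and 5, 22 and 3, 271 and 13, 0 and 541, 400 and 3, 254 and 12, and 39 and 13, in that order, and to 14 and 20 under quantile normalization. Relative to these shifts ccmM, Ni_Fe_hydrogenase, csx14, arsM and pbrA kept their direction under each of these settings, csx14 being too thinly measured for a value in the authors' table and over probes above background on all 10 arrays. Their calls were lost under median scaling (adjusted p = 0.137, 0.0513, 0.135, 0.224 and 0.0513) and under the red-channel standard (adjusted p = 0.998 for each). The authors' table ended the calls of ccmM (adjusted p = 0.0789), Ni_Fe_hydrogenase (0.0789) and arsM (0.251), but not of pbrA (0.00411), and the percentile over probes above background on all arrays ended that of arsM (0.0951). A floor per array ended the calls of Ni_Fe_hydrogenase (adjusted p = 0.0522) and the bymovirus coat protein (0.0555), the restriction to probes above background on all 10 arrays ended that of Ni_Fe_hydrogenase (0.0552), and the slide as a random block ended the call of pbrA (adjusted p = 0.0517). The 4 smaller families also kept their direction under each of these settings that measured them. The red-channel standard ended all 4 calls, median scaling those of the pomovirus (adjusted p = 0.0513) and bymovirus (0.137) coat proteins, common-probe scaling that of the bymovirus one (0.0946), and the slide block those of the bymovirus one (0.0880) and primase (0.0669). Only slide 1 holds both groups, so the slide block cannot fully part slide from group. The slide of 1 array, DNA of soil sample 14, rests on its scan time alone. With medians over probes 15 families passed, 7 higher and 8 lower, 5 of them among the 9. The calls of Ni_Fe_hydrogenase (0.59, adjusted p = 0.276), csx14 (0.32, 0.380), pbrA (-1.68, 0.0556) and arsM (0.052, 0.852) ended there. Among families of at least 10 probes 0 higher and 5 lower passed, since each of the 6 higher families has fewer probes and was not tested. They were arsM and pbrA (adjusted p = 0.0292 for both), and csb1, atzD and xlnd (0.0485 for each), the last 2 of them named after their values were seen.

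Several of these calls were lost with 1 array left out, which also leaves fewer arrays in the test. The differences kept their direction, csx14 at 0.50 to 0.61 and arsM at -0.41 to -0.34. Only ccmM passed with any 1 array left out. Without the DNA array of soil sample 7 it was the only family to pass, with hxuB at an adjusted p of 0.0523 and the pomovirus coat protein at 0.0544. The call of pbrA was lost without DNA 4, 7, 13 or 14 (adjusted p = 0.0521, 0.0743, 0.0623, 0.0552) or cDNA 4, 6 or 13 (0.0839, 0.0734, 0.0673), and that of arsM without DNA 4, 7 or 14 (0.0521, 0.0680, 0.0701) or cDNA 4, 6 or 13 (0.0644, 0.0641, 0.0556). Ni_Fe_hydrogenase lost its call without DNA 7, 13 or 14 (0.0667, 0.0738, 0.0701) or cDNA 4, 6 or 13 (0.0644, 0.0614, 0.0556), and csx14 without DNA 7 or 13 (0.0667, 0.0707) or cDNA 4 or 13 (0.0644, 0.0540). The bymovirus coat protein and primase lost theirs without DNA 4, 7, 13 or 14 or cDNA 4, 6 or 13 (0.0539 to 0.0738 for both). The count of families was 14, 1, 5 and 4 without DNA 6, 7, 13 and 14, and 3, 4, 14, 3 and 21 without cDNA 4, 6, 7, 13 and 14. Without DNA 4, 7 or 14 or cDNA 4, 6 or 13, 0 lower families passed. Of the 21 without cDNA 14, 11 were lower. Without both arrays of soil sample 14, whose cDNA array showed signal on probes for green fluorescent protein, 3 families passed. The call of ccmM held there (adjusted p = 0.00768), and those of Ni_Fe_hydrogenase, csx14, arsM and pbrA did not (0.0969, 0.0638, 0.0969 and 0.0638), nor did those of hxuB (0.0634), the pomovirus and bymovirus coat proteins (0.0638 and 0.0969) or primase (0.0969).

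**Figure D2:**
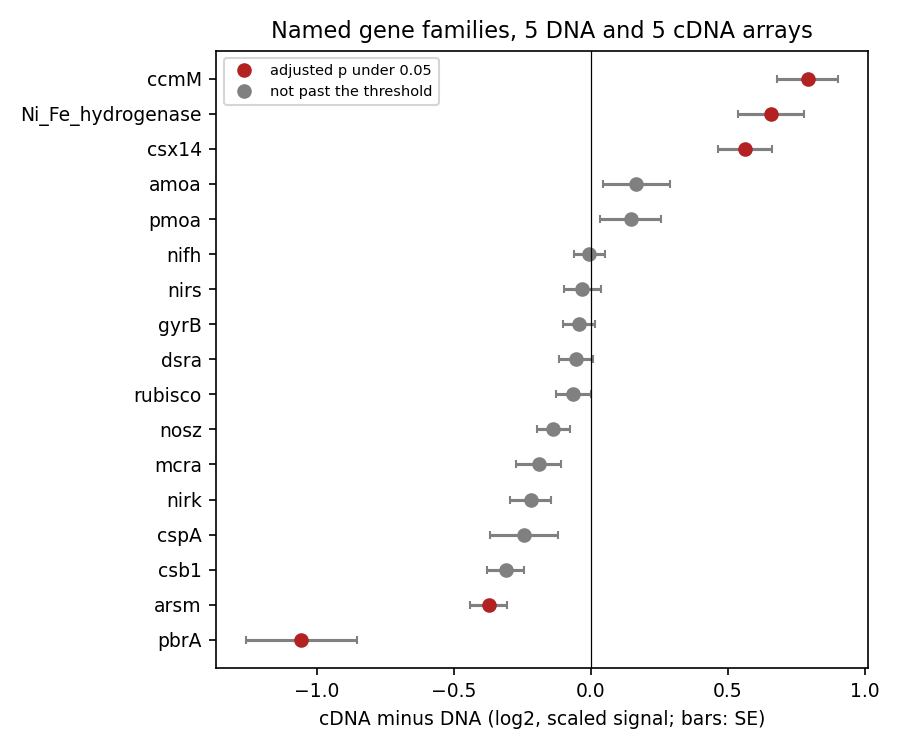
Difference of cDNA minus DNA (horizontal axis, log2 of intensity over the 75th percentile) for 17 named families (vertical axis), with points for the difference of group means (n = 5 each), bars for SE, red for families past the threshold and grey for the rest. ccmM, Ni_Fe_hydrogenase and csx14 lie higher in cDNA by 0.79, 0.66 and 0.56, and pbrA and arsM lower (-1.06 and -0.37).

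Marker genes of the nitrogen, methane and sulfur cycles were named in advance, and limma called 0 of these 11 families. The ammonia monooxygenase gene amoA was at 0.17 (cDNA minus DNA, SE 0.12, adjusted p = 0.460) and the nitrogenase gene nifH at -0.01 (SE 0.06, adjusted p = 0.971). The nitrite reductase genes nirK and nirS were at -0.22 (SE 0.07, adjusted p = 0.126) and -0.03 (SE 0.07, adjusted p = 0.814), and the nitrous oxide reductase gene nosZ at -0.14 (SE 0.06, adjusted p = 0.216). For methane, mcrA of methanogens was at -0.19 (SE 0.08, adjusted p = 0.216) and pmoA of methane oxidisers at 0.14 (SE 0.11, adjusted p = 0.483), with -0.01 on scan date 1 and 0.37 on scan date 2. The sulfite reductase gene dsrA was at -0.05, the carbon-fixing rubisco at -0.06, the cold shock gene cspA at -0.25 and gyrB at -0.04, with adjusted p of 0.639, 0.593, 0.284 and 0.720. In the authors' table, relative to its shift, dsrA, mcrA, nifH and nirS changed sign (0.00, 0.12, 0.11 and 0.14), and over probes above background on all 10 arrays nifH and nirS did (0.03 and 0.02).

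Gene lists fixed in advance were then compared. The carbon fixation list, which does not hold ccmM (0.79), lay lower in cDNA in 12 of 12 tested members, with a median of -0.15. Among them were the Calvin cycle and glycolysis enzyme TIM, triose-phosphate isomerase (-0.28), frdA (-0.27, positive in the authors' table at 0.19 and over probes above background on all 10 arrays at 0.17), the carbon monoxide dehydrogenase codh (-0.26) and PRI, which fell by 0.25. The list passed limma's camera test (adjusted p = 0.0222), and it did not pass with an estimated correlation (adjusted p = 0.995 with an estimated correlation, the correlation being 0.32). Of its members 0 passed over all families and 1, PRI, adjusted over the list alone (adjusted p = 0.0432), or 6 with the soil sample as a block. With that block camera gave an adjusted p of 0.00878, and an adjusted p = 0.781 with an estimated correlation. With scan date as a block it was 0.00372, and within scan dates 1 and 2 it was 0.0253 and 0.299. The array's own carbon fixation subcategory, of 3485 probes, was at -0.14 and lower in 5 of 5 soil samples. It did not pass camera on probe values (adjusted p = 0.999).

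The carbon fixation call was lost without DNA 7 (adjusted p = 0.0519), cDNA 14 (0.0554) or both arrays of soil sample 14 (0.1002), and with a brightness trend removed (0.0504). It was also lost under normexp (0.756), median scaling (0.236), the percentile over probes above background on all arrays (0.835), the red-channel standard (0.880), the authors' table (0.970, direction up), probes above background on all 10 arrays (0.986) and a floor per array (0.617). Relative to the shift of all probes, 12 of 12 members were lower under normexp (median -0.27), median scaling (-0.25), common-probe scaling (-0.13) and with the brightness trend removed (-0.15). The count was 11 under the red-channel standard (median -0.36), with a floor per array (-0.26) and over probes above background on all 10 arrays (-0.18), and 10 in the authors' table (-0.09). Of the 34 lists tested with camera, 33 did not pass (adjusted p of 0.226 or more), and 0 passed with an estimated correlation. Counts for those lists follow as members higher and lower, with calls over all families and adjusted over the list alone.

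Among nitrogen lists, denitrification had 1 member higher and 5 lower of 6, with 0 calls over all families and 3 adjusted over the list alone, or 1 and 4 with the soil block. Adjusted over the list alone, the nitric oxide reductase cnorB rose by 0.44, the respiratory nitrate reductase narG fell by 0.32 (with the soil block adjusted p = 0.0464 over all families) and nirK fell by 0.22, while nosZ at -0.14 did not pass. Assimilatory nitrogen reduction was lower in 5 of 5, with 0 calls over all families and 1 adjusted over the list alone (3 with the soil block), narB, an assimilatory nitrate reductase, which fell by 0.36 and was positive in the authors' table at 0.11. Its nirB, nasA and NiR were at -0.18, -0.18 and -0.17. Dissimilatory nitrogen reduction was lower in 2 of 2, with 0 and 1 calls adjusted over the list alone, nrfA, an ammonia-forming nitrite reductase, which fell by 0.25, beside napA at -0.10. Ammonification was lower in 2 of 2 (gdh and the urease gene ureC at -0.16 each), with 0 and 0 calls, and 2 adjusted over the list alone with the soil block. Nitrification was higher in 2 of 2 (amoA and hao, the last at 0.01 and negative under quantile, median, common-probe and authors' scaling at -0.03, -0.03, -0.03 and -0.09), and anammox in 2 of 2 (hzsA at 0.40 and hzo at 0.17, negative under normexp and the red standard at -0.10 and -0.19), with 0 calls in both, and nitrogen fixation was represented by nifH alone.

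Among metal lists, arsenic was lower in 5 of 5 members, with 1 call over all families and 1 adjusted over the list alone, arsM, or 2 with the soil block, the arsenite oxidase aoxB (-0.30) being the addition. The arsenate reductases arrA and arsC were at -0.23 and -0.12. Copper was higher in 3 of 5, with 0 calls over all families and 1 adjusted over the list alone, the copper and silver efflux gene cusC, which fell by 1.23 (3 probes, adjusted p = 0.00477). In 3 other members the sign turned with scaling, cueO (0.20, and -0.06 in the authors' table), CusA (0.08, and -0.80 in the authors' table) and cusF (0.06, and -0.05 under median scaling). The fifth, copA, named after its values were seen, was at -0.06 (692 probes) and lower in 5 of 5 soil samples and under every scaling. The list's median of 0.06 was positive and its mean of -0.19 negative, cusC being the lowest member, and camera's direction was up. Mercury was higher in 4 of 6 with 0 and 0 calls (merF at 0.27, mer at -0.24, merG at 0.11 and -0.03 under median scaling, merP at -0.09), and mer alone passed adjusted over the list alone with the soil block. Zinc, cadmium, cobalt and nickel was lower in 7 of 12 with 0 and 0 calls (cnrA and rcnA at -0.24 each, nreB and cadBD at 0.21 each, both negative under the red standard at -0.01 and -0.08). Other metals were lower in 10 of 15, with 1 and 1 calls, pbrA, or 2 adjusted over the list alone with the soil block, beside pbrT (0.37), silC (-0.27) and silA (-0.17).

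Among carbon degradation lists, lignin and phenol degradation was higher in 3 of 7, with 0 calls over all families and 2 adjusted over the list alone (3 with the soil block). The manganese peroxidase mnp rose by 0.42 (adjusted p = 0.0117 over the list) and the glyoxal oxidase glx fell by 0.27 (adjusted p = 0.0492), beside the vanillin dehydrogenase vdh (-0.27) and ligninase (0.26). Its median of -0.06 was negative and its mean of 0.01 positive. Starch degradation was higher in 6 of 8 with 0 and 0 calls, or 1 and 2 with the soil block (amylopullulanase, apu, 0.73 with 3 probes and a blocked adjusted p of 0.0369, isopullulanase 0.73, nplT 0.13 and -0.21 in the authors' table, amyA -0.08). Pectin degradation was lower in 4 of 6 with 0 and 0 calls (pel 0.33 and -0.10 under quantile normalization, pme -0.16, rgl 0.09 and -0.01 under median scaling, pec -0.07), its median of -0.05 and mean of 0.02 differing in sign. Cellulose degradation was lower in 4 of 5 (cellobiase -0.16, axe -0.15, exoglucanase 0.10 and -0.01 under the red standard, cdh -0.08 and 0.18 in the authors' table), hemicellulose degradation in 4 of 4 (xylA -0.09, mannanase -0.06, xylanase -0.01, ara -0.01 and 0.04 in the authors' table) and chitin degradation in 2 of 2 (acetylglucosaminidase -0.06 and 0.02 in the authors' table, chitinase -0.03), all with 0 and 0 calls. The glyoxylate cycle was lower in 2 of 2 (AceB -0.19, AceA -0.18) with 0 and 0 calls, and 2 adjusted over the list alone with the soil block.

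For methane, sulfur and phosphorus, methanogenesis was higher in 6 of 9, with 0 calls over all families and 1 adjusted over the list alone, Hmd, a hydrogenase of methanogens, which rose by 0.32, was not called with the soil block (adjusted p over the list = 0.112) and lay at -0.34 over probes above background on all 10 arrays. Its mcrA was at -0.19, mtrA at -0.17 and mtaC at 0.16. Methane oxidation had pmoA at 0.14 and mmoX at -0.01 (0.05 under normexp), with 0 and 0 calls. Sulfur oxidation was lower in 5 of 7 with 0 and 0 calls (soxA -0.57, soxB -0.23, fccAB -0.21 and 0.08 in the authors' table, soxV 0.20 and -0.13 under normexp). Sulfate reduction was lower in 6 of 8 with 0 and 0 calls (AprA 0.25, cysI -0.16, Sir -0.10, cysJ -0.08). Phosphorus genes were lower in 2 of 3 with 0 and 0 calls (ppx -0.08, phytase -0.07, ppk 0.00 and -0.11 under median scaling).

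Among stress and resistance lists, oxidative stress was lower in 6 of 7, with 0 calls over all families and 1 adjusted over the list alone (2 with the soil block), the peroxide-sensing repressor perR, which fell by 0.43, beside katA (-0.21), oxyR (-0.16) and ahpF (-0.16). Cold shock was higher in 2 of 4, with 0 calls over all families and 1 adjusted over the list alone, or 1 and 3 with the soil block. Its member desK, a thermosensing kinase, fell by 0.39 (blocked adjusted p = 0.0353), while desR, its response regulator, was at 0.49, cspA at -0.25 and cspB at 0.10 (-0.22 in the authors' table). Sigma factors were lower in 3 of 4 with 0 and 0 calls, or 3 adjusted over the list alone with the soil block (sigma 32 and 24 at -0.17 each, sigma 70 at -0.13, sigma 38 at 0.11 and -0.05 under the red standard). Oxygen limitation was lower in 6 of 8 with 0 and 0 calls, or 3 adjusted over the list alone with the soil block (arcB 0.27, narH -0.25, fnr -0.16, arcA 0.09). Efflux pumps were lower in 3 of 4 with 0 and 0 calls, or 2 adjusted over the list alone with the soil block (Mex -0.16, ABC -0.15, MFS -0.10, MATE 0.03 and -0.05 under median scaling).

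Heat shock was lower in 5 of 6 (ctsR 0.14, hrcA -0.14, groEL -0.11, grpE -0.09 and 0.17 in the authors' table) and nutrient limitation higher in 7 of 11 (tnrA 0.49, phoB -0.22, bglH 0.19, bglP 0.13 and -0.02 over probes above background on all 10 arrays), both with 0 and 0 calls. Osmotic stress was higher in 2 of 4 (opuE -0.23, proW 0.07 and -0.04 under median scaling, proX -0.03 and 0.02 over probes above background on all 10 arrays, proV 0.01 and -0.07 under median scaling), with camera's direction up and the median at -0.01. Beta-lactamases were higher in 2 of 3 (b_lactamase 0.14 and -0.08 under the red standard, class C -0.14, class A 0.01 and -0.10 under median scaling), and other antibiotic resistance lower in 4 of 7 (fosB -0.44, fosA -0.27 and 0.13 in the authors' table, Van -0.26, vgb -0.22), all with 0 and 0 calls. The annotated subcategories of the array were tested in the same way with camera, where 0 of 114 passed and 2 had an unadjusted p under 0.05. They were the lead subcategory (-0.63, 24 probes, lower in 5 of 5 soil samples) and protist carbon fixation (0.60, 11 probes, higher in 5 of 5), both with an adjusted p of 0.735 and named after their values were seen.

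Lineages were compared as means over their probes. Actinobacteria, soil bacteria that include Streptomyces, were at -0.22 (SE 0.09, 11575 probes), Chlorophyta, green algae, at -0.23 (SE 0.09, 273 probes) and Proteobacteria at -0.10 (SE 0.06, 38414 probes). Microsporidia, parasitic relatives of fungi, were at 0.56 (SE 0.16, 18 probes), Thaumarchaeota, archaea that include ammonia oxidisers, at 0.28 (SE 0.10, 28 probes), Aquificae at 0.21 (SE 0.08) and Bacteroidetes at 0.10 (SE 0.05). In limma 0 of 43 lineages passed and 9 had an unadjusted p under 0.05, the smallest adjusted p being 0.172. The domains Archaea, Eukaryota and Viruses were at -0.04, 0.05 and 0.09, and the kingdom Fungi at 0.06.

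With the soil sample as a block 11 lineages passed, each with the same sign in 5 of 5 soil samples. Microsporidia, Thaumarchaeota, Aquificae, Apicomplexa (0.16), Cyanobacteria (0.12) and Bacteroidetes rose, and Chlorophyta, Actinobacteria, Proteobacteria, Acidobacteria (-0.09) and the domain Bacteria (-0.09) fell. The blocked adjusted p was 0.0221 for Actinobacteria, 0.0232 for Thaumarchaeota, 0.0418 for Apicomplexa and 0.0406 for the rest. Within scan dates 1 and 2 Actinobacteria were at -0.22 and -0.23 and Thaumarchaeota at 0.31 and 0.24. With scan date as a block 4 passed, Actinobacteria (adjusted p = 0.00272), Bacteria, Chlorophyta and Proteobacteria (0.0335 each), and within scan date 1 alone 1 passed. Relative to the shift of all probes the 11 kept their direction under every scaling that measured them, with a floor per array and over probes above background on all 10 arrays, Microsporidia having no value in the authors' table. Without DNA 6, cDNA 7 and cDNA 14, 1, 1 and 2 lineages passed in the unpaired test. The calls split as 34 higher and 0 lower under normexp, 4 and 4 under quantile, 0 and 3 under median, 15 and 0 under common-probe, 0 and 25 under red-standard and 31 and 0 under the authors' scaling, 36 and 0 with a floor per array and 16 and 0 over probes above background on all 10 arrays. With the brightness trend removed 0 lineages passed, with or without the soil block, and the 11 had blocked adjusted p of 0.0820 to 0.170. Their differences were then 0.50 for Microsporidia, 0.22 for Thaumarchaeota, 0.16 for Aquificae, 0.12 for Apicomplexa, 0.09 for Cyanobacteria and 0.06 for Bacteroidetes, and -0.20 for Chlorophyta, -0.16 for Actinobacteria, -0.08 for Proteobacteria, -0.07 for Acidobacteria and -0.07 for Bacteria.

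**Figure D3:**
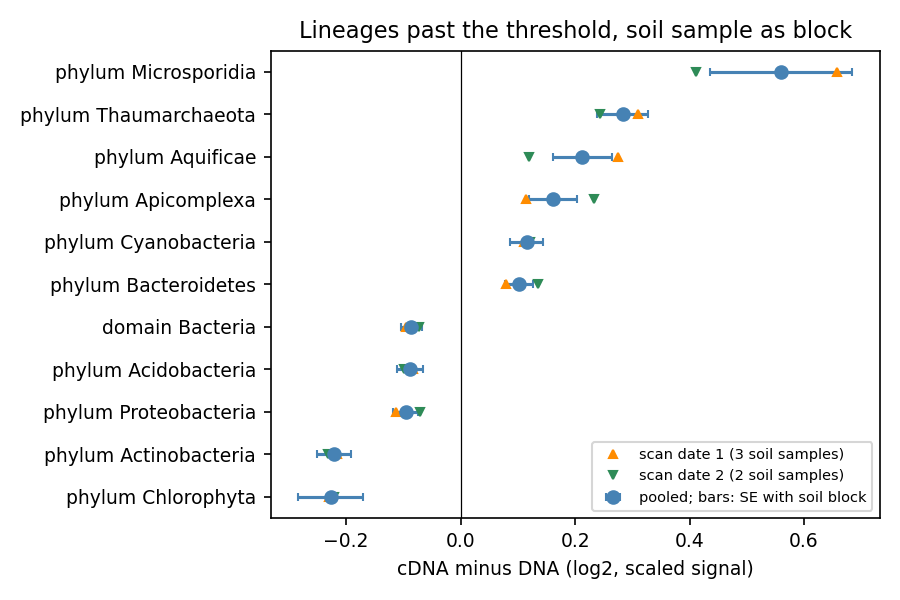
Difference of cDNA minus DNA (log2, horizontal axis) for the 11 lineages past the threshold with the soil sample as a block, with circles and bars for the pooled difference and its blocked SE, and triangles for scan date 1 (3 soil samples) and scan date 2 (2 soil samples). Microsporidia lie at 0.56 and Actinobacteria at -0.22, and both triangles of each lineage lie on the same side of 0.

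Single probes were compared last among the signal tests. A probe for glnA, glutamine synthetase, of Streptomyces scabiei rose by 4.18 (18.1-fold, SE 0.68), one for the chromate transporter ChrA of a Burkholderia rose by 3.55 (SE 0.68), and one for znuC, part of a zinc uptake system, of Roseomonas cervicalis rose by 3.45 (SE 0.44). Probes for the CRISPR-associated cmr6 of Pyrobaculum arsenaticum (3.65, SE 0.89) and iro of Acidovorax avenae (3.33, SE 0.74) rose as well. A probe for silC, a silver efflux gene, of Bordetella petrii fell by 4.35 (SE 0.68), one for amyA, alpha-amylase, of Catenulispora acidiphila fell by 3.84 (SE 0.46) and one for PRI of a gamma proteobacterium fell by 3.86 (SE 0.55). Probes for xylA of Yersinia mollaretii (-3.87, SE 0.92) and the fructose-bisphosphatase FBPase of a Bradyrhizobium (-3.82, SE 0.70) fell as well. Species names are those of the probe's design sequence.

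Limma adjusted p ran from 0.00728 for amyA to 0.0450 for cmr6. All 10 probes had the same sign in 5 of 5 soil samples, as the naming rule required, and so on both scan dates. With the soil sample as a block glnA, ChrA, znuC, PRI and amyA held (adjusted p = 0.0419 each), and cmr6 (0.0734), iro (0.0679), silC (0.0571), xylA (0.0643) and FBPase (0.0579) did not. Leaving out 1 array ended the call of cmr6 in 9 of 10 cases (adjusted p = 0.0599 to 0.103), xylA in 9 (0.0640 to 0.0909), iro in 7 (0.0586 to 0.0852), ChrA without DNA 7 (0.0501) or DNA 13 (0.0534) and FBPase without DNA 7 (0.0509).

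Of 89830 probes 4669 passed, 2186 higher and 2483 lower, 4568 of them with the same sign in all 5 soil samples, and 30 of the lower ones were not well above background on any cDNA array. With the soil sample as a block 2466 passed, 1069 higher and 1397 lower, and 1953 passed both tests. With scan date as a block 5685 passed (2527 higher and 3158 lower), within scan date 1 alone 373 and within scan date 2 alone 0. The split was 1073 higher and 3099 lower under median scaling, 2965 and 1746 under common-probe scaling, 9774 and 4970 under normexp, 0 and 16096 under the red standard, 4789 and 1027 in the authors' table, 6653 and 3763 with a floor per array, and 1676 and 1722 over probes above background on all 10 arrays. Relative to the shift of all probes these became 1457 and 2253, 1926 and 2105, 3192 and 7333, 3 and 1074, 1192 and 2244, 2424 and 5868, and 1111 and 2413. The count was 2010, 2603 and 2319 without DNA 7, 13 and 14, 2714 and 2991 without cDNA 6 and 13, and 2050 without soil sample 14.

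Whether the cDNA of a soil sample resembled its own DNA more than that of other soil samples was tested with probe deviations from the group mean. DNA and cDNA of one soil sample correlated at a mean of 0.0856 across probes (0.0430 to 0.109), and those of different soil samples at -0.0213, or 0.0178 on the same scan date and -0.0474 on different dates. In 5 of 5 soil samples the own partner had the highest correlation. The difference of 0.107 had an exact one-sided p of 0.00833, the smallest that 120 pairings allow, and within scan dates an exact p of 0.0833, the smallest that 12 pairings allow. Probes are not independent replicates, so the pairings of soil samples carried the test.

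The last comparison asked whether profiles varied more between soil samples in cDNA than in DNA, and the difference did not pass the test. The mean distance of an array to its group mean, per probe on the log2 scale, was 0.820 ± 0.104 in DNA and 0.933 ± 0.0686 in cDNA (SD, n = 5, difference 0.113, exact permutation p = 0.0873). Within scan dates 1 and 2 the difference was 0.0631 and 0.187. It passed under quantile normalization (0.140, exact permutation p = 0.00794), over probes above background on all 10 arrays (0.165, exact permutation p = 0.0317), and without the DNA array of soil sample 4, 7 or 14 (0.177, 0.152 and 0.156, exact permutation p = 0.0317, 0.0476 and 0.0397). It was smaller and did not pass without the cDNA array of soil sample 4, 7, 13 or 14 (0.0819, 0.0842, 0.0701 and 0.0609, exact permutation p = 0.246, 0.230, 0.262 and 0.317). Nor did it pass without DNA 6, DNA 13 or cDNA 6 (0.107, 0.0970 and 0.118, exact permutation p = 0.0556, 0.0635 and 0.0794). The distance was larger in cDNA in 5 of 5 soil samples. For these pairs, with the soil sample as a block the exact p was 0.0625, the smallest 5 pairs allow.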

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

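The tests of a single array, of scan date, of carried-over DNA and of the data without soil sample 14 were chosen after the result was seen.

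Rubisco on the cDNA array of soil sample 14 stood far from the other cDNA arrays, at 0.0485 against -0.139 to -0.0876, a gap of 0.725 of the group's range. Of 98 groups of 5 arrays examined in this way 1 held such an array, where chance gives 4.9. Probes for green fluorescent protein, which belong to no soil gene, were well above background on 100% of their 256 spots on that same cDNA array and on 0% to 2.73% on the other 9, a signal in data that no comparison above uses. Their median intensity there was 244. Without both arrays of soil sample 14 the count of families was 3 in place of 9, and the carbon fixation call was lost (adjusted p = 0.1002), with fewer arrays in the test.

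The first pattern is the lower count of probes well above background in cDNA. A single array as its cause is excluded, since the difference stayed at -28919 to -23216 with any 1 array left out. Lower brightness of the cDNA arrays remains a candidate explanation. Counted above 1 common multiple of each array's 75th percentile, cDNA had 4420 more probes than DNA (exact permutation p = 0.0476, n = 5, and 0.0625 with the soil block), -16.9% of the original gap, though scaling by that percentile itself fixes part of this result. Fewer transcribed than carried genes, the biological reading that the DNA and RNA design gives, was not tested apart from brightness and stays open.

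The second pattern is the lower place of Actinobacteria and the higher place of Thaumarchaeota, Bacteroidetes, Cyanobacteria and Aquificae in cDNA, a gap of 0.40 ± 0.08 (SE) on the log2 scale. Scan date as the cause is excluded, since the gap was 0.409 and 0.386 within the 2 dates. A slide effect is not excluded, because most comparisons of cDNA with DNA, all on scan date 2 included, were between slides. With the brightness trend removed the gap was 0.288 ± 0.0837 (SE), 72.0% of its size. That is 3.44 SE above 0 and 1.05 SE above the limit of 0.200 set in advance, which met the rule by a small margin. The phyla in the gap are among those that passed with the soil block on these same arrays, so the distance from 0 is no separate test. The SE takes no account of error in the fitted trend. Brighter lineages were still lower after this step (Spearman -0.55, below), so brightness as the whole cause is not excluded. The single-lineage calls with the soil block went from 11 to 0 at the same step (blocked adjusted p = 0.0820 to 0.170), because the differences shrank to between 56.7% (Bacteroidetes, from 0.10 to 0.06) and 90.0% (Microsporidia, from 0.56 to 0.50) of their size against the same errors, Actinobacteria moving from -0.22 to -0.16 with a blocked SE of 0.0300. Over the 43 lineages, which are not independent, brighter ones were lower in cDNA, with a Spearman correlation of -0.77 between the difference and the DNA level, which also enters the difference, and of -0.67 with the mean level (-0.55 with the trend removed), so the part of the gap that went with the trend may be technical, and a difference in transcription between phyla is a hypothesis that these arrays leave open.

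The third pattern is the signal on 16S ribosomal RNA gene probes, whose log2 ratio to the 75th percentile was 2.55 ± 1.25 in DNA and 0.29 ± 1.16 in cDNA (difference -2.26, exact permutation p = 0.0397, n = 5), lower in 5 of 5 soil samples but with an exact p of 0.0625 with the soil sample as a block, the smallest 5 pairs allow, and -3.21 and -0.84 within the 2 scan dates. All 8 probe positions had a lower mean in cDNA, 5 of them lower in 5 of 5 soil samples (-3.43 to -2.05, exact permutation p = 0.0159 to 0.0397). Positions 874, 1038 and 1368 (-1.11, -1.40 and -1.24) were lower in 3, 4 and 4 and did not pass (exact permutation p = 0.254, 0.119 and 0.119), with 9.96% of spots saturated at position 874 against 0% to 1.05% at the others. Carried-over DNA as the source of the cDNA signal would keep this ratio, but it was lower by 31.2-fold, 9.88-fold, 2.56-fold, 1.94-fold and 1.64-fold in soil samples 4, 7, 14, 13 and 6, the last close to the limit of 1.5 set for the test. Uneven spots as the cause are excluded by differences of -2.33 to -2.17 in 4 equal parts of the array, upper and lower, left and right (exact permutation p = 0.0317 to 0.0397, n = 5, and 0.0625 in each with the soil block). Whether first-strand cDNA can pair with these probes could not be tested without probe sequences, and no biological explanation was tested.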

How the results depend on the processing

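Scan date as a block or alone, the omission of soil sample 14, the floor per array, the removal of the brightness trend and, for that floor and the filter on all 10 arrays, values relative to the shift of all probes, and the soil block for the spread between soil samples, were tests chosen after seeing the data. The cause of a shift was not tested unless stated. The planned GC correction was not run, since no probe sequences were at hand. Signal over background limits cDNA most, at a median intensity of 63.7 against 369 in DNA. The replicate block (soil sample) gave 2466 probes, 20 families and 11 lineages and left the list count at 1. It gave the detection difference of -26197 and the 16S difference of -2.26 an exact sign-flip p of 0.0625, the smallest 5 pairs allow. The 16S difference in each part of the array and the count above a common multiple (4420) had the same p. For the same reason the block took the gene categories with fewer detected probes from 17 to 0. Apart from these and the probe, family, list-member and lineage calls given above it changed no other call that it was run on, the spread difference included (exact sign-flip p = 0.0625). The resemblance test, which rests on the pairs, has no such fit.

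For probes (4669), counts moved to 14744 under normexp, 16096 under the red standard, 1784 under eBayes with trend and robust, 373 and 0 on scan dates 1 and 2 alone (fewer arrays), 2050 without soil sample 14 (fewer arrays) and 10416 with a floor per array, and lay at 2010 to 4812 with 1 array left out. For families (9), they moved to 284 under normexp, 34 under quantile, 25 under common-probe scaling, 541 under the red standard, 403 in the authors' table, 52 over probes above background on all 10 arrays, 61 with scan date as a block, 0 and 0 on scan dates 1 and 2 alone, 3 without soil sample 14, 266 with a floor per array, 15 with medians over probes and 5 among families of at least 10 probes (fewer families tested), and lay at 1 to 21 with 1 array left out. Relative to the shift of all probes the families were 160 under normexp, 72 under quantile, 6 under median, 12 under common-probe scaling, 0 under the red standard, 12 in the authors' table, 33 over probes above background on all 10 arrays and 133 with a floor per array, and the lineages 2, 4, 2, 0, 0, 0, 1 and 2.

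For lists (1), the count was 0 under normexp, median, common-probe and red-standard scaling, in the authors' table, over probes above background on all 10 arrays, on scan date 2 alone, without soil sample 14, with the brightness trend removed, with a floor per array and with an estimated correlation, and 0 to 1 with 1 array left out. For lineages (0), counts were 34 under normexp, 8 under quantile, 3 under median, 15 under common-probe scaling, 25 under the red standard, 31 in the authors' table, 16 over probes above background on all 10 arrays, 4 with scan date as a block, 1 on scan date 1 alone, 36 with a floor per array and 0 to 2 with 1 array left out. Subcategories stayed at 0 under every setting. The detection difference lay at -28919 to -23216 with 1 array left out and at -29055 in the authors' table, and 17 categories had fewer detected probes with any 1 array left out. By another flag of the software, for positive and significant signal, the difference was smaller. It marked 123930 to 136795 target probes on DNA arrays and 104481 to 118508 on cDNA arrays. Category shares gave 0 to 3 calls with 1 array left out. The spread difference rose to 0.140 under quantile normalization and 0.165 over probes above background on all 10 arrays, and lay at 0.0609 to 0.177 with 1 array left out. The resemblance difference kept its direction at 0.0851 under quantile, 0.137 over probes above background on all 10 arrays and 0.104 to 0.132 with 1 array left out.

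A floor per array lies, by its construction, lower on the brighter DNA arrays than on the cDNA arrays, and it moved the median of all probes by 0.36. Over 165 named genes, probes and lineages and all settings, with values relative to such shifts, 3216 values kept their side of the threshold, among them values short of it that changed sign, 204 passed it newly, 104 lost it and 1 changed sign and lost it. That was arsM, at 0.052 with medians over probes, among 19 features past the threshold over all features in the unpaired test. Of 24 past it with the soil block only, 1 changed sign, per_arc, at 0.29 over probes above background on all 10 arrays.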

Other observations

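The tests on other splits of the arrays, the mismatch comparison and the families named here were chosen after the results were seen.

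With the soil sample as a block, 13 further families passed the threshold, narG, desK and apu among them, and 10 others are given here. Lower in cDNA were catechol (-0.40, 221 probes, blocked adjusted p = 0.0353), catB of the catechol pathway (-0.31, 149 probes, 0.0369) and atzD, which opens the ring of cyanuric acid (-0.61, 27 probes, 0.0369), each lower in 5 of 5 soil samples. Lycopene epsilon cyclase, a carotenoid gene, fell by 1.05 (9 probes, 0.0187), the peroxidase families per_bac and per_arc by 0.43 and 0.46 (0.0353 and 0.0369), mce3 by 0.73 (4 probes, 0.0187) and sped_fungi by 0.61 (7 probes, 0.0470). The CRISPR-associated csm4 rose by 0.36 (23 probes, 0.0498) and lpfA by 0.60 (4 probes, 0.0353). All 10 had the same sign within both scan dates and, where measured, under every scaling and with a floor per array, but per_arc over probes above background on all 10 arrays lay at 0.29. None of these passed in the unpaired test, where the smallest adjusted p among them was 0.0531 for atzD.

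Perfect-match probes were set against their mismatch partners on the 48 of 313 pairs whose perfect match was above background on all 10 arrays. The array medians of the log2 ratio were 2.38 ± 0.46 in DNA and 2.39 ± 0.27 in cDNA (SD, n = 5, difference 0.02, exact permutation p = 0.937). The mismatch probe was the brighter one in 14.6% to 20.8% of these 48 pairs on DNA arrays and in 12.5% to 20.8% on cDNA arrays. With both probes above background on all 10 arrays, 21 pairs, the ratios were 1.02 ± 0.32 and 0.94 ± 0.57 (exact permutation p = 0.802). The mismatch was then brighter in 28.6% to 38.1% of pairs on DNA arrays and 23.8% to 47.6% on cDNA arrays. Over all 313 pairs, dim ones included, it was brighter in 46.6% to 50.5% and 40.6% to 47.0% (exact permutation p = 0.0159). Over the pairs whose perfect match was above background on the array itself, it was brighter in 31.8% to 41.9% on DNA arrays and 14.1% to 27.7% on cDNA arrays. The median log2 ratios of these pairs were 0.46 to 1.49 and 1.62 to 2.77. Such pairs differ from array to array, and no test was run on them. The 48 pairs thus do not show how well probes in general told matches apart.

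Of 126 ways to split the 10 arrays into 5 and 5, 100 were drawn, the real one included. For probes 1 of 100 splits, the real one, gave as many calls (4669, highest other 0), and for families 1 of 100 (9, highest other 1), so chance is excluded for both counts over splits that ignore the pairing of arrays by soil sample. For lists 5 of 100 gave as many (1, highest other 1), so chance is not excluded for the carbon fixation call. For subcategories and lineages the real count was 0, which 100 of 100 splits reach, with a highest other of 0 and 9. The split with 9 lineages set DNA 4, 7 and 14 and cDNA 4 and 7, 5 of the 6 arrays of scan date 1, against the rest. The other drawn splits that kept 5 of these 6 arrays together gave 0 lineages, so these splits do not settle whether lineages follow scan date. Levels of Actinobacteria were lower on scan date 2 than on scan date 1 within each group. They were 0.585 and 0.669 against 0.871 to 0.883 in DNA, and 0.371 and 0.421 against 0.608 to 0.731 in cDNA. In Bacteroidetes the dates overlapped. Each soil sample was scanned on 1 date, so date and soil sample cannot be told apart here. The difference of cDNA minus DNA in Actinobacteria was -0.22 and -0.23 within scan dates 1 and 2. The 14 drawn splits that part all 5 pairs, as the real one does, are too few for a share under 0.05, and the highest other counts among them were 0 probes, 0 families, 0 lists and 1 lineage.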
